A study of Mus musculus with 4 samples.

How the data were processed

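RNA of sorted mouse LT-HSCs was measured in 4 libraries, 2 from WT and 2 from ATF4 KO mice, grouped by their sample titles. HISAT2 2.2.1, featureCounts, DESeq2 and the genome build GRCm38 are named without their order in the submitters' processing notes. The deposited table gives 1 log2 value per gene and library. Which transform made the values is not stated. Its last line stops inside the values of 1 gene and was left out. The 4167 complete lines cover most of chromosome 1 (98.7% of its genes in GENCODE M21) and the start of chromosome 2. Genes elsewhere were not analysed here. Of the symbols, 98.5% matched GENCODE M21, which gave the coordinates and gene types on GRCm38.

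The form of the log2 values was worked out from the deposited numbers. They met the equation of a regularized logarithm, in which each library's term in a negative binomial model is shrunk towards the gene's mean, with a ridge weight of 0.1645 and a lower limit of 0.5 on fitted reads. The size factors of the ATF4 KO libraries came from 297 genes with 0 reads in both, which met the equation with a largest residual of 6.08e-08. Every gene with a value fell clearly into the class with 0 reads in both or outside it, with 0 genes between. The WT size factors came from 195 of those genes, whose implied WT reads had a median distance of 0.097 from whole numbers. Of these reads 51.0% were within 0.1 of a whole number. The WT size factors and ridge weight were chosen to make this distance small, so it is no independent check. WT reads are given rounded. Where 1 ATF4 KO library had 0 reads and the gene lay on the dispersion trend, the implied reads of the other were within 0.1 of a whole number in all 203 genes. Reads in both ATF4 KO libraries were recovered for 93 more genes, by that trend, and 233 genes were left without reads. WT reads were recovered only for WT means above 2. On 1928 simulated genes with known reads and the same size factors, the class of 0 reads in both was right for 100% of genes, and both ATF4 KO read numbers were exact for 100% of the 807 genes recovered.

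The design written before the data were examined expected counts or linear normalized values. As the values were already logarithms, limma 3.58.1 (R 4.3.3) was fitted to them as they are, with no pseudocount, a prior variance that follows the level, and robust estimation (statmod 1.5.0). Genes needed a value of at least 1 in at least 2 libraries. Differences are ATF4 KO minus WT on the deposited log2 scale. That scale is shrunk, and for genes with 0 reads in both ATF4 KO libraries the size and direction of a difference depend on the transform. P-values were adjusted by Benjamini and Hochberg, with a threshold of 0.05. They reflect the spread between these libraries, which cannot be assigned to animals. Values were simulated for the 1199 tested genes, with each gene's WT mean and the same spread in all 4 libraries. There limma found 51% of 200 genes changed by 1 and 65% of 200 genes changed by 2. It made 4 and 5 false calls, and 0 calls with no gene changed. The simulation had neither genes with 0 reads placed by the transform nor a wider spread in ATF4 KO. Its false calls thus do not give the rate of false calls in the data.

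Expected reads are the mean of the normalized WT reads times the summed size factors of the ATF4 KO libraries. Where both had 0 reads, 3 reads over the pair were taken as the limit, and ratios with reads have exact 95% Poisson intervals. These cover counting error only.

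The named genes followed a rule fixed beforehand. It took the 8 largest differences per direction among genes past the threshold, with an average level of at least 3 and both ATF4 KO libraries beyond both WT libraries, without predicted models, pseudogenes, sex-linked genes and receptor segments. Where fewer than 4 passed, the genes of lowest p made it 4. Up to 4 genes of lowest p were added from each list with a set call or 2 members past the threshold, from the ATF4 target lists and from the list of genes higher in aged HSCs, and a fixed set of 12 genes where present. Of 34 gene lists, 7 had no member in the part analysed and 24 had a tested member. Lists with at least 5 tested members were tested with limma's camera (correlation 0.01), and with fry as an alternative.

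Alternatives chosen beforehand were no filter, a minimum difference of 1, a replicate block, each library left out, an estimated correlation and fry. Others, chosen after the values were seen, were no trend in the prior, a lowest value of 3, genes with an ATF4 KO read only, and limma's voom on the recovered reads with the size factors as library sizes. Similarity of gene models to mitochondrial transcripts was found with BLAST 2.17.0 (at least 90% identity over at least 50% of the transcript). Permutation tests and Poisson intervals used scipy 1.17.1 and numpy 2.4.6.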

Results

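Long-term haematopoietic stem cells (LT-HSCs) are the rare bone marrow cells that renew themselves and give rise to all blood lineages. They were sorted by flow cytometry from the marrow of wild-type (WT) mice and of mice with a conditional knockout of Atf4 (ATF4 KO). ATF4 is the transcription factor of the integrated stress response, which switches on genes of amino acid synthesis and transport. Polyadenylated RNA was sequenced after a library preparation derived from Smart-seq2, a method for very small amounts of RNA. There were 2 libraries of each genotype, and the labels do not say whether each came from a separate animal. The comparison asks which transcripts differ when stem cells lack ATF4, in a study of stem cell decline that resembles ageing.

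The values were read up to the last complete line of the table, which held 4167 genes in chromosome order. Of these, 3377 matched genes on chromosome 1 of the mouse genome GRCm38 and 727 matched genes on chromosome 2, up to position 31460738, and the matched genes were 7.43% of the annotated genes. Atf4 lies on chromosome 15, so its level in the 4 libraries was not analysed here and the genotype labels could not be checked against it. The values were on a log2 scale, with 2239 genes at exactly 0 in all 4 libraries and 1928 genes with other values.

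The libraries of the 2 genotypes differed greatly in depth. Of the 1928 genes, the read numbers behind the values were recovered for 1695 in the ATF4 KO libraries and for 675 in the WT libraries, and with them each library's size factor, the relative depth used to normalise it. The size factors were 21.7 for WT 1, 17.1 for WT 2, 0.0360 for ATF4 KO 1 and 0.0372 for ATF4 KO 2. The ATF4 KO libraries thus had 0.166% and 0.171% of the depth of WT 1. Of the 1928 genes with values, 1399 had 0 reads in both ATF4 KO libraries. Among the 660 genes with a WT mean above 3 on the log2 scale, 244 had 0 reads in both. A gene with 0 ATF4 KO reads was not listed at 0, because the transform placed it between the gene's own mean and a fixed value, 2.36 in ATF4 KO 1 and 2.31 in ATF4 KO 2. Of 677 tested genes with 0 reads in both, the 353 with WT means below these values were thus higher in ATF4 KO and the 324 above them lower.

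**Figure D1:**
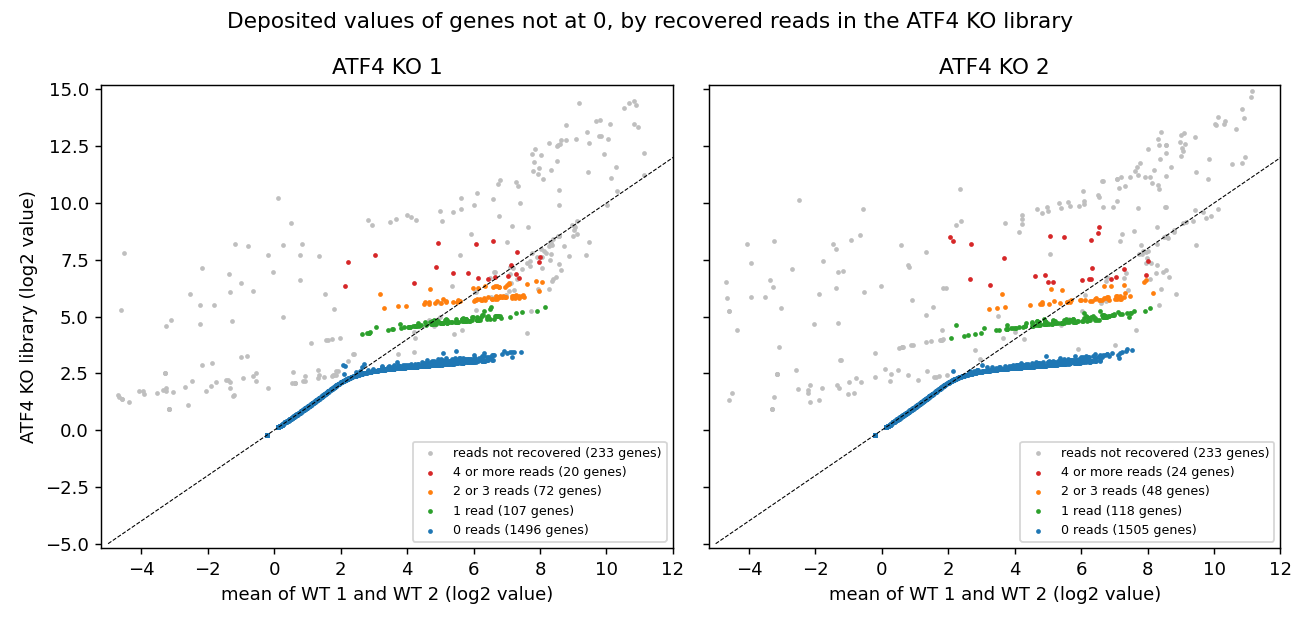
Each point is a gene with a value other than 0, placed by its mean deposited log2 value in the 2 WT libraries (horizontal) and its log2 value in ATF4 KO 1 or ATF4 KO 2 (vertical), and coloured by the reads recovered in that ATF4 KO library; the dashed line marks equal values. The 1496 genes with 0 reads in ATF4 KO 1 and the 1505 in ATF4 KO 2 form the lowest band, genes with 1 read form the next, and for low WT levels the band of 0 reads lies on the line of equal values.

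Among the named genes, the largest decreases on the deposited log2 scale were those of Stk16, Tor3a, Nmt2, Ptp4a1, Itih5, Uck2, Uap1l1 and Atp6v1h. Stk16 encodes a kinase of the Golgi region, Nmt2 an enzyme that attaches myristate to proteins, Uck2 a kinase of pyrimidine nucleoside salvage and Atp6v1h a subunit of the proton pump that acidifies lysosomes. Stk16 (chromosome 1, 75210838 to 75215606) was at 7.15 ± 0.11 in WT and 3.20 ± 0.02 in ATF4 KO (log2 value, mean ± SD, n = 2 each). The difference was -3.96 with a standard error of 0.29 (limma, adjusted p = 0.00366). It was -4.03 without WT 1 and -3.88 without WT 2. The differences of the other 7 genes lay between -3.49 for Tor3a (chromosome 1, 156653617 to 156674356, adjusted p = 0.00345 by limma) and -3.28 for Atp6v1h (chromosome 1, 5070018 to 5162529, adjusted p = 0.00308 by limma). All 8 genes had 0 reads in both ATF4 KO libraries, against 1423 to 3346 reads in single WT libraries. Their ATF4 KO values and small SDs were thus set by the transform. The order of the 8 genes followed their WT levels and does not rank the decreases.

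By counting error alone, the recovered reads would set a lower bound on these decreases. At its WT level and the size factors, Stk16 would have given 11.95 reads over both ATF4 KO libraries. As 0 reads allow up to 3 over the pair, Stk16 would be at least 3.98-fold lower. The same bound was at least 2.61-fold for Tor3a and at least 2.19-fold for Atp6v1h. These bounds cover counting error only, and reads amplified by PCR are not independent molecules. They make no allowance for picking the 8 genes by their differences. Zeros were also more common than counting error gives. Among genes with a WT mean above 3, it predicts 87.7 with 0 reads in both, and 244 were seen. A decrease of these genes is thus not established. Across 389 genes with WT levels between 3 and 6, the ATF4 KO libraries held 311 reads, 40.1% of the number expected from the size factors. This yield is a low estimate, since 24 further genes at these levels, whose reads were not recovered, are not counted. At that lower yield the bound was 1.60-fold for Stk16, 1.05-fold for Tor3a and 1.04-fold for Nmt2, and the other 5 genes had no bound above 1. These genes had WT means of 6.33 to 7.15, above the range in which the yield was measured. The same holds below wherever the lower yield is applied to genes with WT levels above 6.

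Of 30 HSC identity genes, 2 were in the part of the genome analysed, and 1 of them was lower in ATF4 KO, as were 268 of all 1199 tested genes. Gfi1b, a transcriptional repressor of blood stem and progenitor cells, was at 6.01 on average in the WT libraries and at 3.01 and 2.98 in the ATF4 KO libraries. It fell by 3.01 with a standard error of 0.18 (limma, adjusted p = 0.00286; 0.00114 when adjusted over the list alone). It had 0 ATF4 KO reads, which by counting error alone would make it at least 1.76-fold lower at the size factors. At the lower yield 2.11 reads were expected and Gfi1b had no bound. Cd34, a surface protein of progenitors that LT-HSCs carry at low levels, differed by -1.24 with a standard error of 0.56 and did not pass (limma, adjusted p = 0.186).

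Of 36 genes known to be higher in aged HSCs, 3 were tested. None was higher in ATF4 KO, 2 were lower over all genes tested, and the same number were lower when adjusted over the list alone. Of all 1199 tested genes 268 were lower, and 3 genes are too few to compare with that share. Cavin2, a coat protein of caveolae (chromosome 1, 51289126 to 51302960), was at 4.60 and 5.26 in WT and at 2.87 and 2.84 in ATF4 KO. It fell by 2.07 with a standard error of 0.29 (limma, adjusted p = 0.0152). Slamf1, which encodes the stem cell marker CD150 (chromosome 1, 171767127 to 171801184), was at 3.76 and 3.33 in WT and at 2.70 and 2.67 in ATF4 KO. It fell by 0.86 with a standard error of 0.18 (limma, adjusted p = 0.0424). Both had 0 ATF4 KO reads, but only 2.59 reads of Cavin2 and 1.004 of Slamf1 were expected over the pair at WT levels, so a decrease of either was not detectable at this depth by the reads themselves. With voom, limma's method for read counts, on the recovered reads, the estimate for Slamf1 was 0.02 (adjusted p = 0.947). Voom also gives a library with 0 reads a fixed value, so this estimate does not measure a level in ATF4 KO. With no trend in limma's prior, the adjusted p was 0.0543 for Cavin2 and 0.1 for Slamf1. Selp, the adhesion protein P-selectin (chromosome 1, 164115264 to 164150026), was at 6.03 and 5.85 in WT and at 4.83 and 3.11 in ATF4 KO and did not pass (limma, adjusted p = 0.144). Fits without 1 ATF4 KO library take their spread from WT alone, so only their differences are given. Selp differed by -2.83 without ATF4 KO 1 and by -1.11 without ATF4 KO 2. It had 1 read in ATF4 KO 1 and 0 in ATF4 KO 2, and the ratio of that 1 read to the 4.83 expected had a 95% exact Poisson interval from 0.00524 to 1.15.

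Direct ATF4 targets were nearly absent from the part analysed. None of the 14 genes of amino acid and one-carbon synthesis and none of the 12 amino acid transporters was in it. Of 19 stress regulators controlled by ATF4 only Atf3 was (chromosome 1, 191170296 to 191218039), at -0.21 in all 4 libraries with 0 reads in both ATF4 KO libraries, too low to be tested. Among 20 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids and include ATF4 targets, 3 were tested and none passed, over all genes tested or adjusted over the list alone. Dars differed by -1.47 ± 0.54 (SE), Farsb by -0.98 ± 0.65 and Eprs by -0.46 ± 0.51. Over the pair of ATF4 KO libraries, Dars had 6 reads against 19.9 expected at the size factors, a ratio of 0.302 with a 95% exact Poisson interval from 0.111 to 0.656, whose upper end was 1.64 at the lower yield. Farsb had 4 of 7.86 expected reads and Eprs 13 of 19.2, with upper ends of 1.30 and 1.16.

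Nuclear genes of the mitochondrial respiratory chain formed the only list with at least 5 tested members, and 1 of its 7 members passed. Atp5c1, the gamma subunit of ATP synthase, fell by 2.66 with a standard error of 0.39 (limma, adjusted p = 0.0176). It had 1 read in each ATF4 KO library, against 20.4 expected over the pair, a ratio of 0.0981 with a 95% exact Poisson interval from 0.0119 to 0.354, whose upper end was 0.884 at the lower yield. The interval covers counting error only, and reads varied by more than that. Between WT 1 and WT 2 the mean squared deviation of reads was 10.9 times the counting variance (median 4.28) over 675 genes. Atp5c1 also had the lowest p of its list. A decrease of Atp5c1 is thus not established. When adjusted over the list alone, 0 members passed, with 1 at an unadjusted p under 0.05 in limma. Cox5b, a subunit of cytochrome c oxidase, differed by 1.48 ± 1.56 (SE), and the other 5 members by -0.56 (Ndufs1) to -2.50 (Ndufa10), none of them past the threshold. The list as a whole did not pass against the other genes (limma's camera, preset correlation of 0.01, adjusted p = 0.167, and adjusted p = 0.449 with an estimated correlation of 0.222). Without the filter on low values the list passed (adjusted p = 0.00728 by camera). Camera compares the list with the other tested genes, many of which had ATF4 KO values set by the transform. That call thus does not show a fall of the list by itself.

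Over the 34 gene lists fixed beforehand, 46 different genes were tested, and of these 9 were lower and 1 was higher. Of all 1199 tested genes 268 were lower and 295 higher, so the lists did not hold a larger share of either. Besides the genes above, the lower ones were Il1r1, the receptor of interleukin 1 (-1.93 ± 0.09, SE), Notch1 (-0.69 ± 0.08), the DNA repair gene Parp1 (-3.22 ± 0.73) and Hsd17b7 of cholesterol synthesis (-0.25 ± 0.03). Parp1 had 1 read in ATF4 KO 2 and 0 in ATF4 KO 1, and the other 3 had 0 in both. The ratio of that 1 read to the 14.5 expected had a 95% exact Poisson interval from 0.00174 to 0.383, with an upper end of 0.957 at the lower yield. At WT levels only 2.26 reads of Il1r1, 0.858 of Notch1 and 0.558 of Hsd17b7 were expected over the pair, so a decrease of these 3 was not detectable at this depth by the reads. The 1 higher gene was the immediate early gene Ier5, by 0.09 ± 0.01 (SE), with 0 reads in both ATF4 KO libraries. Markers of myeloid cells did not pass. Fcer1g, the signalling chain of Fc receptors, was at 10.89 in both WT libraries and at 14.31 and 13.73 in ATF4 KO (limma, adjusted p = 0.0564). Its reads were not recovered, so how far the transform set these values is not known. Cxcr2 differed by -0.25 ± 0.12 (SE) and Fcgr3 by -0.70 ± 1.10. The cell cycle genes Mcm3 (-1.37 ± 0.52, SE), Mcm6 (-2.02 ± 0.86), Mcm10 (-1.51 ± 0.72) and Cenpf (-1.92 ± 0.73) did not pass, nor did the ribosomal protein genes Rpl7 (1.99 ± 0.79), Rpl31 (1.98 ± 1.56), Rpl37a (2.54 ± 0.83) and Rpl7a (0.49 ± 1.35). Xrcc5, the other DNA repair gene tested, differed by 0.50 ± 2.10 (SE) and did not pass. It had 18 reads, all in ATF4 KO 2, against 3.17 expected over the pair, and Rpl7a had 16, of which 15 were in ATF4 KO 2, against 5.70. Of 23 named genes and list members with an ATF4 KO read and recovered reads, 9 had ratios to the expected reads with exact Poisson intervals below 1 and 2, Xrcc5 (3.36 to 8.96) and Rpl7a (1.60 to 4.56), above 1. At the lower yield these were 2 and 2. All these intervals, that of Parp1 included, cover counting error only, so none establishes a change.

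Few named genes were higher in ATF4 KO. Chst10, a sulfotransferase (chromosome 1, 38863867 to 38898161), was at 1.81 ± 0.57 in WT and 4.88 ± 0.66 in ATF4 KO (mean ± SD, n = 2 each), a rise of 3.07 with a standard error of 0.52 (limma, adjusted p = 0.024). The reads of Chst10 were not recovered in any library, so their ratio to the expected reads is not known. At low WT levels the transform itself can place a gene with an ATF4 KO read above WT. How much of the rise of Chst10 came from this was not tested. Armc9, a gene of the primary cilium (chromosome 1, 86154780 to 86278284), rose by 0.85 with a standard error of 0.14 (limma, adjusted p = 0.0244). It had 1 read in each ATF4 KO library and 267 and 239 reads in WT, and the ratio to the 0.959 reads expected had a 95% exact Poisson interval from 0.253 to 7.53. Without WT 1 Chst10 rose by 3.48 and Armc9 by 0.78, and without WT 2 by 2.67 and 0.93. Those fits take their spread from ATF4 KO alone, so only the differences are given. Itih2, of the inter-alpha-trypsin inhibitor family (chromosome 2, 10094593 to 10131396), and Fcer1g completed the list of 4 without passing, with differences of 3.07 and 3.13 (adjusted p = 0.0536 and 0.0564 by limma). With no trend in limma's prior both passed (adjusted p = 0.0228 and 0.0211) and Chst10 did not (adjusted p = 0.0755). Itih2 and Fcer1g also passed with a lowest value of 3 (adjusted p = 0.0392 and 0.0347 by limma). Without ATF4 KO 1 they differed by 3.37 and 2.84, and without ATF4 KO 2 by 2.77 and 3.42. The spread in those 2 fits comes from WT alone, so only the differences are given. In 112 genes with a WT mean above 6 whose reads were not recovered, the WT libraries differed by a median of 0.0265, against 0.127 in 135 others. The WT values of Itih2 had an SD of 7.31e-05 and those of Fcer1g an SD of 0.0042. The reads of neither gene were recovered, and the transform draws each library towards the gene's mean. How much of their WT levels and differences it set was not tested.

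**Figure D2:**
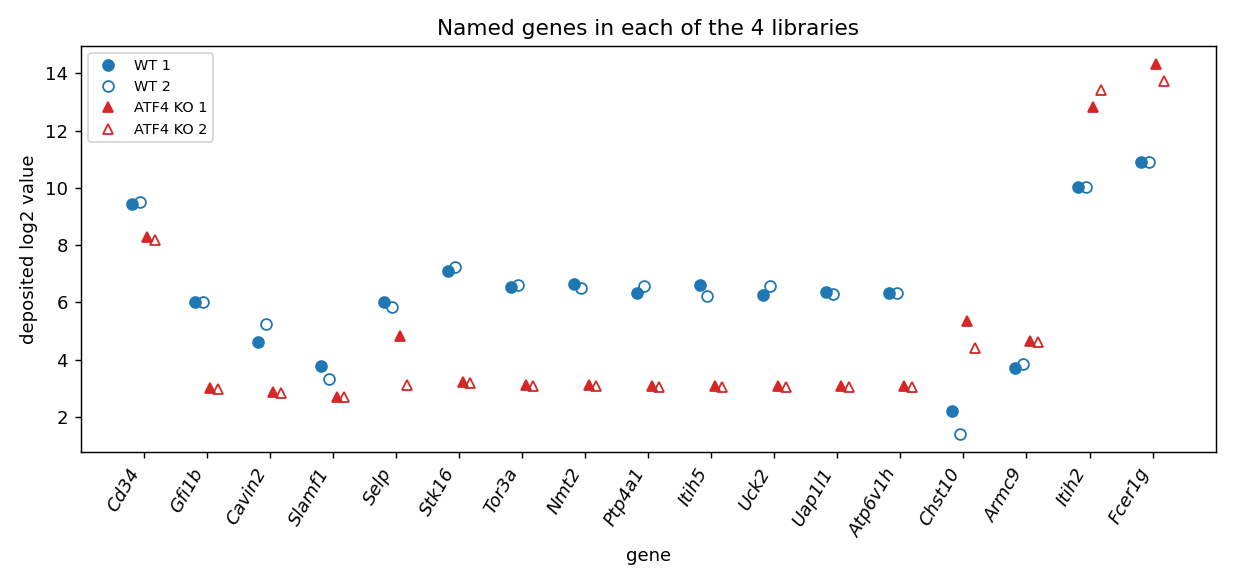
Deposited log2 values (vertical) of 17 genes in each library, with circles for WT and triangles for ATF4 KO and open symbols for replicate 2. From Gfi1b to Atp6v1h the ATF4 KO symbols near 3 are libraries with 0 reads of the gene, as the 3.20 of Stk16 is; ATF4 KO 1 has 1 read of Selp, at 4.83.

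In all, 1199 genes had a value of at least 1 in at least 2 libraries, and 563 differed between the genotypes (limma, adjusted p under 0.05), 295 higher and 268 lower in ATF4 KO. Without ATF4 KO 1 there were 881 (461 lower), and without ATF4 KO 2 there were 862 (464 lower). The lower genes had 0 reads in both ATF4 KO libraries in 257 of 268 cases, with differences of 0.10 to 3.96 in size. The higher genes had 0 reads in both ATF4 KO libraries in 283 of 295 cases, and each of these 283 was higher by less than 0.1. Of the higher genes 11 were higher by at least 1, and 8 of those are pseudogenes. This count was 5 without WT 1, 6 without WT 2, 128 without ATF4 KO 1, 99 without ATF4 KO 2 and 97 with voom on the recovered reads. Among the 522 tested genes with a read in an ATF4 KO library, none passed when they were tested alone, with 78 at an unadjusted p under 0.05 (limma). The WT libraries differed from each other with an SD of 0.261 over tested genes, and the ATF4 KO libraries with an SD of 1.96. An exact permutation test of 2 against 2 libraries cannot give a two-sided p below 0.333, so the calls rest on limma's estimate of the spread. In the 257 lower and 283 higher genes with 0 reads in both ATF4 KO libraries, the transform gave those libraries nearly the same value. Their spread in ATF4 KO is thus small whatever their true variation.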

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

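The alternatives with no trend, a lowest value of 3, genes with an ATF4 KO read and voom were chosen after the data were seen. The 563 calls (295 higher, 268 lower) became 1315 without the filter (1037 higher), with 1928 genes tested. A minimum difference of 1 left 203 (11 higher). With no trend in the prior there were 291 (28 higher), and with a lowest value of 3 there were 255 (15 higher). Among genes with an ATF4 KO read there were 0 calls, 0 higher and 0 lower; that choice removes the genes whose ATF4 KO values agree because both libraries had 0 reads. Voom on the recovered reads called 281 of 675 genes, 123 higher and 158 lower, with a median difference of -0.36 over these genes against 0.018 over the 1199; 152 of the 268 lower genes were lower there too, and 22 were called higher. Under voom Slamf1 went from -0.86 to 0.022, with 0 ATF4 KO reads. Voom gives a library with 0 reads a value fixed by its library size, so neither estimate measures such a gene's ATF4 KO level. Leaving out 1 library gave 634 to 881 calls, 302 to 464 of them lower, highest without an ATF4 KO library, where the lone sample is assumed to vary like WT.

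The camera test of the respiratory chain (adjusted p = 0.167) gave 0.00728 without the filter, 0.0124 among genes with an ATF4 KO read, 0.0025 to 0.322 with 1 library left out, and 0.897 in the other direction with a lowest value of 3; the cause was not tested. Limma's fry, which tests the list against no change and not against other genes, gave 0.0129. With the replicate number as a block there were 510 calls (277 higher, 233 lower), and camera gave 0.173. The labels do not state whether the replicate numbers pair the samples. Across genes the differences WT 1 minus WT 2 and ATF4 KO 1 minus ATF4 KO 2 correlated at -0.076. This correlation cannot decide whether they do. In the 677 tested genes without a read in either ATF4 KO library, the transform gave those libraries nearly the same value. Of 137 values of the 15 tested named genes under alternatives, 115 kept direction and side of the threshold, 11 lost the call, 10 gained it and 1 reversed. The planned count-based alternatives and the pseudocount were not run, as the values are logarithms. The depth of the ATF4 KO libraries limits every result.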

Other observations

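The tests below were chosen after the results were seen, except the 2 permutation tests within bins of WT values. Outside the rule for named genes, and chosen after their values were seen, gene models that copy mitochondrial DNA stood out. In the part analysed, 10 models matched a mitochondrial transcript over at least 98.2% of their length: 7 on chromosome 1 between 24611535 and 24616197 and 3 on chromosome 2 between 22587291 and 22590533 (GRCm38). The 9 with values had ATF4 KO reads and were above WT by more than 0.5 in both ATF4 KO libraries. For low WT levels the transform gives this to any gene with an ATF4 KO read: all 53 other genes with such a read and a WT mean below 0 were above WT in the same way. In 5 models both ATF4 KO values were at least 6.26, as in 1 of 142 other genes with an ATF4 KO read and a WT mean no higher than the models'. In the other 4 models 1 ATF4 KO library was at 0.91 to 2.13. Gm28437, identical to mt-Co3 (cytochrome c oxidase subunit III), was at -1.42 and -0.93 in WT and at 8.20 and 7.02 in ATF4 KO. Gm13340, a copy of mt-Co1, was at 4.05 and 4.19 in WT and at 9.37 and 8.75 in ATF4 KO. The models made up 5 of the 11 genes that were higher by at least 1, beside 3 processed pseudogenes, the antisense model Gm16152, Gm2000 and Chst10.

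Reads of mitochondrial transcripts given to these nuclear copies are a candidate explanation that stays open. The lower of the 2 ATF4 KO values had a median of 6.26 in the 9 models and 2.45 in the 142 other genes (permutation test of the rank sum, two-sided, p = 0.267). Whether reads shared with pseudogenes in general were handled differently in the ATF4 KO libraries stays open too. Of 187 processed pseudogenes, 34 were above WT by more than 0.5 in both ATF4 KO libraries, which at low levels amounts to having an ATF4 KO read. Of 1130 protein-coding genes, 54 were. Shuffling within bins of the deposited WT mean gave 24.1 ± 2.35 (SD) pseudogenes (permutation test, two-sided, 100000 resamples, p = 0.0002). Through the transform the deposited WT mean depends on the ATF4 KO reads. The bins thus do not match genes on WT expression alone, and the test cannot decide this. Whether ATF4 KO cells held more mitochondrial RNA cannot be told apart from these explanations, since 0 genes encoded by mitochondrial DNA were in the part analysed.

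The 257 lower genes with 0 reads in both ATF4 KO libraries may in large part reflect depth. At WT levels 80.5% of them (207) would have given fewer than 3 reads over the pair. At the yield of 40.1%, a low estimate that leaves out 24 genes without recovered reads, 3 of the 257 would have given 3 or more. Counting error at the size factors is not enough alone: among genes with a WT mean above 3 it predicts 87.7 with 0 reads in both, and 244 were seen. If particular genes had fallen in both ATF4 KO samples, their zeros should coincide. Among 389 genes 234 had 0 reads in both, against 232.7 ± 3.48 (SD) by chance at equal WT level (permutation test, one-sided, p = 0.402), but 24 genes without recovered reads keep this open, since p would be 0.00046 if all had reads in both libraries and 0.84 if all had reads in 1.

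Of the 283 genes higher by less than 0.1, 100% had 0 reads in both ATF4 KO libraries. Their direction followed from the transform, which places a library with 0 reads between the gene's own mean and a fixed value set by its size factor, so it says nothing about their level in ATF4 KO. No biological explanation was tested for these.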
